A study of Prochlorococcus marinus str. NATL2A and Alteromonas macleodii
Prochlorococcus marinus str. NATL2A with 42 samples.

How the data were processed

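RNA was sequenced from cultures of Prochlorococcus NATL2A, a small marine cyanobacterium, with and without Alteromonas MIT1002, a heterotrophic marine bacterium. Per the labels' protocols, the cyanobacterium grew in seawater-based PRO99 medium under constant light, the heterotroph was added to a set of replicate cultures at about the same cell abundance, and medium alone was added to the axenic set. Samples were taken 12 h before the addition and 2, 4, 6, 12, 24 and 48 h after it. At each time 3 replicate cultures of each set gave a library, which makes 14 groups and 42 libraries. Per the labels' protocols, total RNA came from cells held on filters, libraries were strand-specific (dUTP marking of the second strand), and a duplex-specific step lowered ribosomal RNA. Such a step acts on abundant molecules of any kind, so the levels of the most abundant transcripts may be compressed in all libraries.

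The deposited table holds whole-number read counts per gene and library, not normalized, for 2198 genes of Prochlorococcus and 4136 genes of Alteromonas, with RAST annotation per the file header. Per the submitters' processing notes, SAMtools 0.1.19 and HTSeq were used. The aligner, the genome build, the HTSeq version and the strand setting of the counting are not given in the sources used here, so no genome positions are printed, and genes that overlap or lie antisense to another gene stay uncertain. Reads shared by near-identical copies could have been split or dropped by such counting, and values of single members of the high-light-inducible family and of the short FIG00940767 family are uncertain for that reason. Gene symbols came from the RefSeq annotation of assembly ASM1246v1, which paired 1980 of the 2198 Prochlorococcus genes and gave 529 of them a symbol; 886 Prochlorococcus genes are annotated as hypothetical or unknown. The only non-coding RNA the annotation names, rnpB, held 0.833 to 3.54% of the Prochlorococcus counts of a library and was left out of library sizes and tests.

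Total counts per library ran from 402894 (axenic, 2 h, replicate 2) to 2902720. Shares of counts carry exact Clopper-Pearson intervals at 95%. A count of 0 was bounded by a floor of 3 counts summed over the 3 libraries of a group. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of replicates was the same library deposited again: the chi-square per degree of freedom between replicates was 2.05 or more in all 42 pairs.

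Prochlorococcus counts as deposited were tested with the quasi-likelihood F-test of edgeR 4.0.16 (R 4.3.3, limma 3.58.1). All 42 libraries entered 1 fit with a mean for each of the 14 groups, which left 28 residual degrees of freedom. The labels do not say whether the same cultures were sampled again at each time; the fit and the tests over time treat all libraries as independent, and their p-values rest on that. Deviations from the group mean of libraries with the same number and set correlated across times by -0.01 to 0.08 on average (single pairs -0.38 to 0.47), though the numbers need not follow a culture. Library sizes were scaled by TMM on Prochlorococcus counts alone, so that Alteromonas reads did not enter them. A gene was tested when it passed filterByExpr with its minimum count of 10, which kept 2147 genes. P-values were adjusted by Benjamini-Hochberg within each contrast, and a gene was called at an adjusted p under 0.05. The contrasts were co-culture against axenic at each time, the departure of that difference from the difference 12 h before addition, and an F-test over the 6 differences from the time before addition among the axenic cultures. Levels are given as CPM on the TMM-scaled Prochlorococcus library sizes, as mean ± SD of 3 libraries; log2 fold changes carry the standard error of the fit. Alteromonas genes were tested in the same way in a separate fit of the 18 co-culture libraries after addition, with TMM on Alteromonas counts; 3286 of its genes passed the filter. The axenic libraries and those before addition serve as the background for Alteromonas counts.

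Gene lists were written as symbol and product patterns before the data were examined, as were the tests, the rule for named genes and all alternatives but those without libraries that stood apart or without axenic libraries with raised Alteromonas counts, which were chosen after seeing the data. Of 34 lists 33 were used; a list meant for conserved non-coding RNA matched 10 genes, all protein-coding, and was dropped. Each list with at least 3 tested members was tested with camera at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry; adjustment was over the 33 lists of a time. Lists of Alteromonas genes, of the Pcb antenna proteins and of all 21 annotated high-light-inducible genes (the fixed pattern took 19) were written only after the annotation was seen. The photosystem II list also takes the Pcb genes, whose products name that complex.

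The rule for named genes took, at each time after addition, the 6 largest rises and falls among called genes with a product whose 3 co-culture libraries all lay on one side of the 3 axenic ones (which chance gives in 10% of genes), the 2 largest hypothetical ones each way, up to 4 called members of each list with at least 3 called members, and a fixed panel of 30 genes whatever their test showed. For Alteromonas it took the 6 largest rises and falls with a product at 48 h against 2 h. The rule held a further clause: where most of the called genes have no name, genes are given by ID, at most 2 each way. Of the 285 genes called at 1 time or more, 123 (43.2%) have a product, so the clause came into force. List members and the panel are named by their own parts of the rule; other genes with a product are named here as well and count as chosen after their values were seen.

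The gene tests were tried on simulated counts, drawn for each gene independently, with 200 genes changed. In the comparison at 48 h, edgeR recovered 77% of 1.5-fold and 93% of 2-fold changes among 2141 genes, with 4 false calls of 174. The test of departure from the difference before addition recovered 47% and 81%, the axenic time test 74% and 96%, and the Alteromonas time test 17% and 86% at these sizes. The list tests were tried with 1 list of 20 genes lowered 1.5-fold beside 20 unchanged lists. Each called the lowered list. Of the unchanged lists camera called 0 with either correlation and fry called 1. These genes were drawn independently too, so the trial cannot show how often lists of correlated genes are called falsely. The alternatives were DESeq2 1.42.0 (a likelihood ratio test for the tests over several times, since a Wald test takes a single difference), other size factors, no low-count filter, rnpB kept, counts thinned to the smallest library, fits on fewer libraries, the replicate number as a block and each replicate left out. Python 3.11.15 with SciPy 1.17.1 drew the plots and ran the exact tests.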

Results

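Transcripts of Prochlorococcus NATL2A were counted in 42 libraries: 3 co-cultures with Alteromonas MIT1002 and 3 axenic cultures at each of 7 times, from 12 h before the heterotroph was added to 48 h after. The design asks how the cyanobacterium's transcripts change once a heterotroph shares its medium. Total counts per library ran from 402894 to 2902720, and counts on Prochlorococcus genes from 402774 to 2902550. The biological coefficient of variation among replicates was 0.101.

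Alteromonas transcripts appeared in the co-cultures soon after the addition and took a growing share of the counts until 12 h. Their share of a library's counts was 2.54% ± 0.18 at 2 h (SD, n = 3), 6.79% ± 0.24 at 4 h, 10.7% ± 0.71 at 6 h and 26.1% ± 3.61 at 12 h. It was 15.96% ± 0.71 at 24 h and 14.4% ± 0.43 at 48 h. The 18 co-culture libraries after addition held 49480 to 719184 Alteromonas counts. The 6 libraries from before addition held 93 to 126 such counts, and the 18 axenic libraries after it held 89 to 1929, with a median of 143.5. The highest of these axenic values were 1219 counts at 6 h (replicate 3), 449 at 12 h (replicate 1) and 1929 at 48 h (replicate 2).

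**Figure D1:**
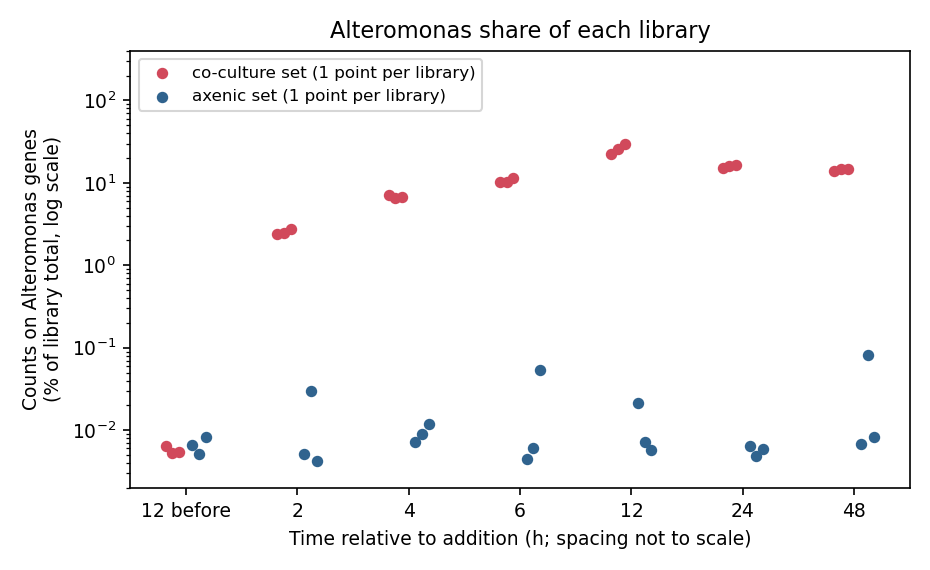
Counts on Alteromonas genes in percent of the library total (log axis), 1 point per library, at each time relative to the addition. The co-cultures reached 22.6 to 29.8% at 12 h, while the axenic library with the most Alteromonas counts lay at 0.0827%.

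Before the heterotroph was added, edgeR called no gene between the sets of cultures over all genes. This comparison gives the baseline difference between the sets. Of 2147 genes tested 0 were called, 68 had an unadjusted p under 0.05, and DESeq2 also called 0. Of 33 gene lists 0 were called by camera. Adjusted over its list of 6 antenna and phycoerythrin genes alone, the linker PMN2A_1677 passed upward in the co-culture set (1.16 ± 0.36, adjusted p = 0.0159), as did another linker, PMN2A_1678, at 2 h (0.59 ± 0.15, 0.00263). That adjustment does not cover the other lists, and over all genes neither was called (edgeR adjusted p = 0.999 and 0.135).

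In the first 6 h few Prochlorococcus genes were called between the cultures, and their number depended on the libraries fitted. At 2 h 1 gene was called, the hypothetical gene PMN2A_1710, at 31.5 ± 2.41 CPM in co-culture and 10.5 ± 4.09 in axenic culture (log2 fold change 1.70 ± 0.32, adjusted p = 0.0101). At 4 h edgeR called 0 genes, with 233 at an unadjusted p under 0.05, DESeq2 called 0, and 1 was called without axenic replicate 1. At 6 h 5 genes were called, all lower in co-culture. They included PMN2A_0508, a high-light-inducible gene (-0.52 ± 0.10, adjusted p = 0.00752), and PMN2A_0509 and PMN2A_0553 (-0.47 ± 0.08 and -0.45 ± 0.09), members of the hypothetical family FIG00940767. The high-light-inducible list fell as a group at 6 h, with a median of -0.29, and the call held with an estimated correlation (adjusted p = 5.8e-12 by camera, 0.0348 with an estimated correlation, 0.0172 by fry). Of its 19 members 1 was called over all genes and 10 adjusted over the list alone. The count at 6 h rests on single libraries: it was 0 without co-culture replicate 1 or axenic replicate 3, and 3 without co-culture replicate 3 or axenic replicate 2. The gene at 2 h was no longer called without co-culture replicate 3 or axenic replicate 1, and 4 genes were called without axenic replicate 2 and 5 without axenic replicate 3. With only the 6 libraries of the time 2, 29 and 25 genes were called at 2, 4 and 6 h, and after thinning 0, 2 and 4. Library totals only gave 16 genes at 6 h. Without 3 libraries that stood apart, a choice made after seeing the data, 5 genes were called at 2 h and 18 at 6 h. Without the 3 axenic libraries with the most Alteromonas counts, also left out after seeing the data, 0 were called at 6 h.

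Some lists moved at these early times by camera alone. The high-light-inducible list had medians of -0.15 at 2 h and -0.22 at 4 h (adjusted p = 0.0284 and 0.0110), with adjusted p = 0.903 and 0.566 with an estimated correlation. Photosystem I had medians of 0.20 and 0.19 (adjusted p = 0.0284 and 0.0116), with the same p of 0.903 and 0.566 with an estimated correlation. At 6 h carbon fixation and carboxysome genes (median 0.11, adjusted p = 0.00333), ATP synthase (0.11, 0.0127) and photosystem II (0.08, 0.00333) were called upward, with adjusted p = 0.782 for each with an estimated correlation, and 0 of their members were called. The Pcb antenna list, written after the annotation was seen, had a median of 0.20 at 6 h (adjusted p = 0.00379, and 0.25 with an estimated correlation).

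By 12 h a family of small stress proteins had dropped in co-culture. High-light-inducible proteins bind chlorophyll and are known for protecting the photosynthetic membrane under excess light and other stress. Of the list's 19 tested genes 12 fell, with a median of -0.79 over the list. PMN2A_0508 stood at 200 ± 7.67 CPM against 468 ± 37.8 in axenic culture, 2.34-fold lower (-1.23 ± 0.11, adjusted p = 1.3e-11), and PMN2A_0577 at 314 ± 8.16 against 726 ± 74.0 (-1.21 ± 0.11, adjusted p = 2.0e-11). PMN2A_1716 and PMN2A_0551 fell by 1.20 ± 0.12 and 1.39 ± 0.16 on the log2 scale (adjusted p = 2.4e-10 and 3.1e-08). In each of these genes all 3 co-culture libraries lay below all 3 axenic ones. The list was called by camera (adjusted p = 2.7e-25), with an estimated correlation (adjusted p = 0.000385) and by fry (1.6e-08), and 12 members fell adjusted over the list alone. Single members are uncertain where near-identical copies could share reads.

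Of the 91 genes called at 12 h, 87 were lower and 4 higher in co-culture, and 50 of the lower ones had changed at least 2-fold. The hypothetical gene PMN2A_0476 fell 4.82-fold, from 89.7 ± 10.3 CPM in axenic culture to 18.4 ± 3.58 (-2.27 ± 0.18, adjusted p = 8.8e-13). The chaperone gene clpB (PMN2A_0016), which rescues aggregated proteins, was at 188 ± 14.9 against 272 ± 9.32 CPM (-0.53 ± 0.11, adjusted p = 0.00129). It was the only one of the 30 genes of the fixed panel past the threshold at any time. Rises were small: Maf (PMN2A_0769), named for septum formation, rose by 0.74 ± 0.20 (adjusted p = 0.0178), and the hypothetical genes PMN2A_2012 and PMN2A_2021 by 0.50 and 0.32. Most of the rise of PMN2A_2012 was there before addition, since its departure from that difference was 0.09 (adjusted p = 0.999), against 0.53 (0.728) for Maf and 0.40 (0.0496) for PMN2A_2021. The Maf call was lost under 9 alternatives. After thinning 60 genes were called at 12 h.

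**Figure D2:**
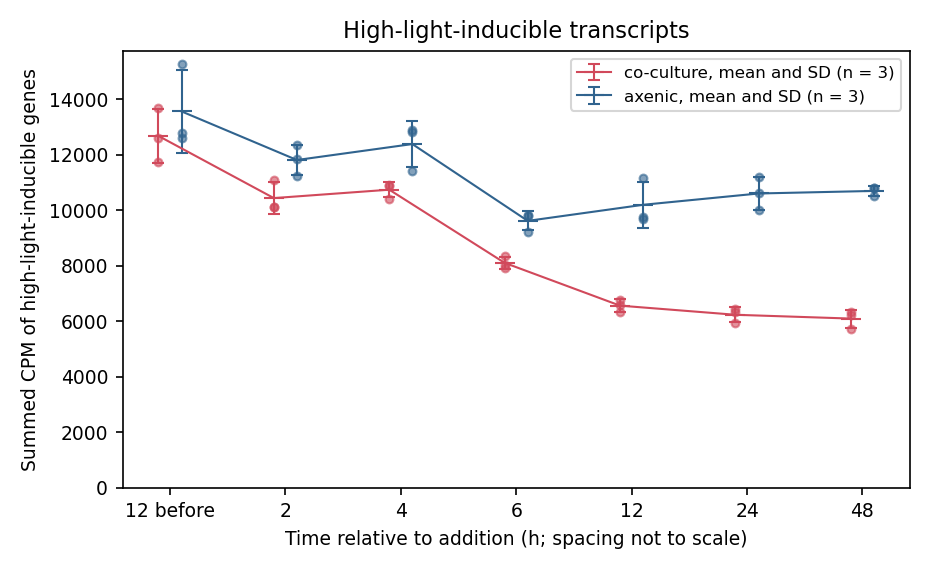
Summed CPM of the 21 annotated high-light-inducible genes in co-culture and axenic libraries at each time; points are libraries, bars mean and SD (n = 3). At 48 h the co-cultures lay at 6101 ± 327 and the axenic cultures at 10701 ± 173.

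At 24 and 48 h the high-light-inducible genes stayed lower in co-culture. Of the 19 genes 13 fell at 24 h and 14 at 48 h, with medians of -0.95 and -1.03. At 24 h PMN2A_1716 was at 222 ± 42.4 against 529 ± 38.8 CPM (-1.26 ± 0.12, adjusted p = 6.9e-11), and PMN2A_0602 fell by 1.22 ± 0.12. At 48 h PMN2A_0508 fell by 1.21 ± 0.11 (adjusted p = 1.8e-11) and hli11 (PMN2A_0941) was at 878 ± 60.6 against 1792 ± 78.4 CPM (-1.03 ± 0.11, adjusted p = 1.0e-09). The list was called by camera (adjusted p = 3.2e-22 and 2.7e-25), with an estimated correlation (0.000926 and 0.000355) and by fry (1.5e-09 and 3.6e-10); adjusted over the list alone, 13 and 14 members fell and 1 rose at each time, PMN2A_0886 (0.46 and 0.50, not called over all genes). Over all 21 annotated genes, 13, 14 and 15 fell at 12, 24 and 48 h. The summed CPM of these 21 genes was 93.5% of the axenic value before addition (exact two-sided permutation p = 0.5), 88.4% at 2 h, 86.7% at 4 h, 84.3% at 6 h, 64.4% at 12 h, 58.8% at 24 h and 57.0% at 48 h. At each time after addition the exact permutation p was 0.1, the smallest that 3 against 3 libraries can give. Not every member fell: PMN2A_1013 (hli2) was at 0.02, 0.08 and 0.06 at 12, 24 and 48 h.

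Other genes fell beside them. At 24 h 215 genes were called, 135 lower and 80 higher in co-culture, and at 48 h 181, of which 122 were lower and 59 higher. At least 2-fold changes numbered 47 lower and 18 higher at 24 h, and 55 and 17 at 48 h. Of the genes lower at 12 h, 64 were also lower at 24 h, where independent lists would share 5.47, and 92 were lower at both 24 and 48 h against 7.67; 42 were higher at both 24 and 48 h against 2.20. At all 3 times 62 genes were lower and 0 higher. Of these 62, 13 were high-light-inducible and 43 hypothetical. The remaining 6 have a product and were named after their values were seen: the diflavin flavoproteins PMN2A_1375 (-0.38, -0.36 and -0.33 at 12, 24 and 48 h) and PMN2A_1376 (-0.49, -0.40 and -0.39), enzymes known for passing electrons to oxygen, an alkyl hydroperoxide reductase-like protein PMN2A_0727 (-0.84, -0.56 and -0.78), the NADPH-dependent reductase PMN2A_0390 (-0.45, -0.91 and -0.71), the protein PMN2A_0467 of family PM-17 (-1.45, -1.06 and -1.05) and bioD (PMN2A_1002) of biotin synthesis (-0.44, -0.45 and -0.55). The largest fall among hypothetical genes was that of PMN2A_2055, from 4.68 ± 1.04 to 0.673 ± 0.257 CPM at 24 h (-2.68 ± 0.50) and by 2.33 at 48 h. PMN2A_2055 was not called by DESeq2, and bioD was no longer lower at 24 h after thinning. The count at 24 h was 119 without axenic replicate 1, 127 without co-culture replicate 3 and 140 without co-culture replicate 2; it was 330 with only the 6 libraries of the time and 117 after thinning. At 48 h it was 108 without co-culture replicate 3 and 111 without axenic replicate 1.

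**Figure D3:**
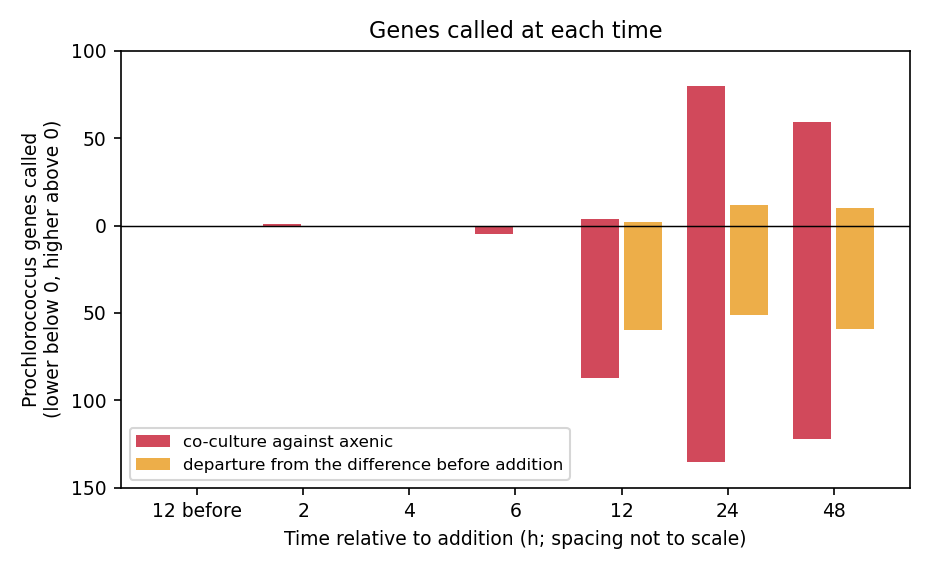
Prochlorococcus genes called at each time, lower ones below 0 and higher ones above 0, for co-culture against axenic cultures and for the departure from the difference before addition. Calls were mostly downward at 12 h (87 lower, 4 higher) and went both ways at 24 h (135 lower, 80 higher).

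Several genes of photosynthesis rose at 24 h. Of 11 photosystem I genes 6 rose, with a list median of 0.37, and 8 rose adjusted over the list alone. psaD (PMN2A_1150) was at 737 ± 29.0 against 545 ± 46.8 CPM (0.44 ± 0.11, adjusted p = 0.00598), and psaF (PMN2A_1801) rose by 0.37 ± 0.10 (adjusted p = 0.00985). The reaction centre genes psaA and psaB were at 0.23 and 0.11 (adjusted p = 0.319 and 0.697) and did not pass. The photosystem I list was called by camera at 24 h (adjusted p = 6.95e-04) and fry (0.00247) but not with an estimated correlation (adjusted p = 0.462); at 48 h its median was 0.28 and 1 member was called (adjusted p = 0.00309 by camera, 0.00776 by fry, 0.724 with an estimated correlation). bchL (PMN2A_1872), the iron-sulfur subunit of the light-independent protochlorophyllide reductase of chlorophyll synthesis, was at 1167 ± 282 against 586 ± 85.8 CPM at 24 h (0.99 ± 0.21, adjusted p = 6.3e-04) and 0.87 ± 0.21 at 48 h (adjusted p = 0.00372). Subunit N of the same enzyme, PMN2A_1873, rose by 0.37 ± 0.09 (adjusted p = 0.00541), and hemL fell by 0.35 ± 0.12 (adjusted p = 0.0498). The 42 genes higher at both 24 and 48 h also had median log2 differences of 0.47 at 2 h and 0.46 at 4 h, and -0.09 at 6 h. psaD was not called without axenic replicate 1 or with library totals only, psaF not without co-culture replicate 2 or 3 or axenic replicate 1, and bchL at 48 h not without co-culture replicate 3.

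Further genes with a product were called at 24 and 48 h. Rises with a product were PMN2A_0619 of family PM-14 (1.45 ± 0.25 at 24 h and 1.43 at 48 h), PMN2A_0944 (1.52 ± 0.31 and 1.40), annotated as a possible hemagglutinin-neuraminidase, and the phycobilisome linker PMN2A_1678 (0.70 ± 0.14 at both times). Of the NADH dehydrogenase list ndhL and nuoB rose by 0.58 and 0.27 at 24 h while PMN2A_1446 fell by 0.58. Of the cofactor list cobO rose by 0.51, and bioD, cbiD and nadA fell by 0.45, 0.48 and 0.39. The fall of bioD at 24 h was lost after thinning. Of the transporter list chrA, the ATP-binding protein PMN2A_1455 and PMN2A_1891 fell by 0.70, 0.44 and 0.36. At 48 h the sigma factors PMN2A_1305 and PMN2A_0013 rose by 0.41 ± 0.11 and 0.47 ± 0.14 (adjusted p = 0.0108 and 0.0261) and PMN2A_1207 fell by 0.24 ± 0.08 (0.0390). These lists were not called by camera: at 24 h adjusted p was 0.719 for NADH dehydrogenase, 0.837 for cofactors and 0.983 for transporters, and at 48 h 0.296 for RNA polymerase and sigma factors. The hypothetical genes PMN2A_2049 and PMN2A_1971 rose by 2.20 ± 0.50 and 1.95 ± 0.34 at 24 h, and PMN2A_2049 and PMN2A_0525 by 2.37 and 2.20 ± 0.42 at 48 h. Fry alone also called DNA repair (downward, adjusted p = 0.027), cytochrome b6f and electron carriers (upward, 0.0083) and antenna and phycoerythrin genes (upward, 0.00666) at 24 h, and DNA repair (0.00776) and antenna genes (0.0334) at 48 h. In the simulated counts, drawn without correlation between genes, fry also called 1 of 20 unchanged lists.

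**Figure D4:**
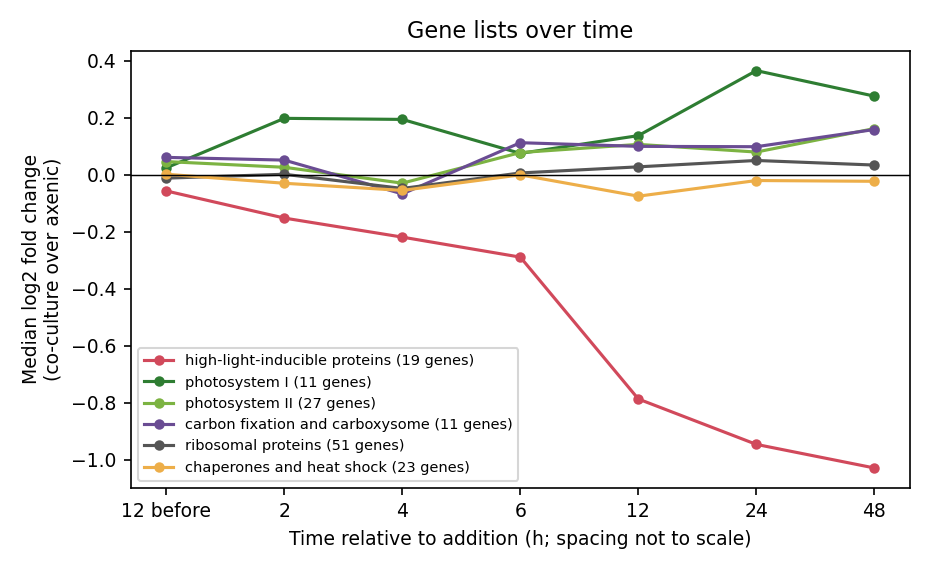
Median log2 fold change of co-culture over axenic culture for 6 gene lists at each time. The high-light-inducible list reached -1.03 at 48 h and photosystem I 0.37 at 24 h.

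The difference at 12, 24 and 48 h was tested against the one before addition. The question is which genes moved between the cultures after the addition. At 2, 4 and 6 h edgeR called 0 genes, with 95, 100 and 106 at an unadjusted p under 0.05, and DESeq2 called 0. At 12 h 62 genes departed (60 lower, 2 higher), at 24 h 63 (51 lower, 12 higher) and at 48 h 69 (59 lower, 10 higher). The count at 24 h was 105 without the 3 libraries that stood apart and 41 after thinning; at 48 h it was 42 after thinning and 45 with only the 12 libraries of 48 h and of the time before addition. Of the 21 high-light-inducible genes 13, 11 and 13 departed downward. clpB departed by -0.62 at 12 h (adjusted p = 0.0176) and bchL by 1.05 at 24 h (adjusted p = 0.0353).

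In the axenic cultures, with no heterotroph, 586 genes (27.3%) changed over the 7 times, and 111 of them were also called between the cultures. With no batch label, a change of the cultures cannot be told apart here from a difference between the library sets of each time. Against 12 h before the addition, 322 genes were called at 6 h (97 higher, 225 lower), 46 at 2 h, 86 at 4 h, 62 at 12 h, 94 at 24 h and 145 at 48 h. Ribosomal protein genes fell at 6 h in 30 of 51 cases, with a list median of -0.30 (adjusted p = 1.8e-15 by camera, 0.0159 with an estimated correlation), and 16 and 21 of them fell at 24 and 48 h (0.0140 and 0.0089 with an estimated correlation). At 2 and 12 h 3 and 12 of them fell (2.2e-09 and 3.5e-09 by camera, 0.0894 and 0.109 with an estimated correlation), and at 4 h 2 fell with no call of the list (0.487 by camera). Carbon fixation genes fell at 2 h in 8 of 11 cases (median -0.53, adjusted p = 9.8e-16 by camera and 0.0658 with an estimated correlation), in 0 at 4 h and 12 h, and in 10, 8 and 8 at 6, 24 and 48 h (0.121, 0.0825 and 0.182 with an estimated correlation). The high-light-inducible genes fell here too, without the heterotroph: 13 of 19 fell and 1 rose at 6 h (median -0.52, adjusted p = 1.7e-07 by camera, 0.121 with an estimated correlation). At 12, 24 and 48 h 7, 6 and 8 of them fell, with medians of -0.38, -0.32 and -0.37 (0.109, 0.199 and 0.275 with an estimated correlation). The heme A synthase gene PMN2A_1778 went from 726 CPM before addition to 1227 at 4 h and 665 at 6 h (adjusted p = 3.0e-09), and rpsM from 3946 to 2651 at 6 h. Without axenic replicate 1, 2 or 3 the count of genes changed over time in axenic cultures was 268, 299 or 327. It was 1127 with library totals only, 267 after thinning and 307 without the 3 axenic libraries with the most Alteromonas counts. Of 36 list calls by camera in the axenic cultures 33 ended with an estimated correlation.

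Alteromonas transcripts changed far more. Of 3286 genes 2526 (76.9%) changed over the 6 times after addition; the axenic cultures hold no Alteromonas control. TMM takes most genes as unchanged, while most were called here, so the folds and list medians hold only relative to that scaling. After thinning the count was 1284. Against 2 h, 374 genes were called at 4 h (182 higher, 192 lower), 509 at 6 h, 1292 at 12 h (719 higher, 573 lower), 1536 at 24 h and 1387 at 48 h. Ribosomal proteins, the parts of the protein-making machine, fell: 54 of 54 at 12 and 24 h and 52 at 48 h, with medians of -3.29, -2.96 and -2.29 (adjusted p = 0.00153, 0.0184 and 0.0200 with an estimated correlation). At 4 and 6 h 29 and 48 of them fell (medians -0.53 and -0.91, 1.1e-16 and 1.1e-36 by camera), without a call with an estimated correlation (0.284 and 0.0893). Chaperones, which fold proteins, rose in 7 of 13 cases at 4 h and 8 at 6 h (0.00773 and 0.0407), with no call of the list at 12, 24 or 48 h. Amino acid synthesis genes rose in 17 of 52 cases at 4 h and 19 at 6 h (0.00934 and 0.0407) and fell in 27 at 12 and 24 h and 25 at 48 h (0.0267, 0.0246 and 0.0200). Of 82 flagella and chemotaxis genes 13 fell and 1 rose at 4 h, and 14 fell and 1 rose at 6 h (medians -0.56 and -0.27, adjusted p = 6.3e-04 and 0.0047 by camera, 0.284 and 0.464 with an estimated correlation). At 12 h 29 rose (median 0.63, 0.00890 by camera, 0.349 with an estimated correlation), at 24 h 59 rose and 2 fell, with a median of 1.57, or 1.56 with genes of no counts at their bound (0.0475 with an estimated correlation), and at 48 h 42 rose and 2 fell (1.04, 5.0e-05 by camera, 0.182 with an estimated correlation). Proteases rose in 40 of 84 cases at 12 h and 35 at 24 h (0.00922 and 0.0475) and were not called at 4, 6 or 48 h. Polysaccharide breakdown genes rose in 9 of 17 cases at 12 h (0.0313) and were not called at other times. TCA and glyoxylate genes fell in 18 of 26 cases at 24 and 48 h (0.0246 and 0.0200), and in 16 at 12 h by camera (0.0089) but not with an estimated correlation (0.183). Peroxide removal genes rose in 9 of 13 cases at 24 h by camera (adjusted p = 0.0338) but not with an estimated correlation (0.279). TonB-dependent receptors, iron uptake, mobile elements, nitrogen regulation, phosphate acquisition and type IV pili were not called.

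**Figure D5:**
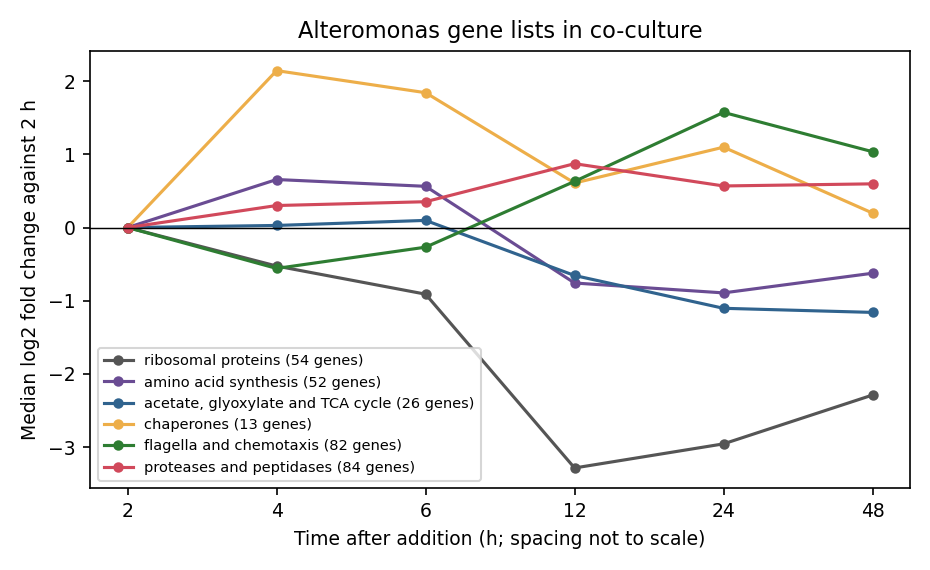
Median log2 fold change against 2 h for 6 lists of Alteromonas genes in co-culture. Ribosomal proteins reached -3.29 at 12 h while flagella and chemotaxis reached 1.57 at 24 h.

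Single Alteromonas genes moved by several orders of magnitude between 2 and 48 h. Phage shock protein A (MIT1002_3400), a membrane stress protein, had 0 counts at 2 h and 5620 at 48 h, at least 227-fold higher against a floor of 3 counts over the group. The response regulator MIT1002_0492 was at least 42.4-fold higher, the SpoVR-like MIT1002_0302 at least 34.5-fold, signal peptidase I (MIT1002_3318) at least 19.4-fold and the amino acid permease MIT1002_4013 at least 13.3-fold. These bounds put the 0 at 2 h at the floor and take the counts at 48 h as exact. With counting error at both times, the exact 95% intervals had lower limits of 185, 34.4, 28.0, 15.8 and 10.7-fold. They are lower mainly because the interval allows more than 3 counts behind the 0 at 2 h. SprB (MIT1002_1667) went from 3 counts (23.5 CPM) to 26595 ± 7685 CPM, a ratio of 1137 (95% interval 389 to 5511). Aldehyde dehydrogenase (MIT1002_3629) fell from 18009 ± 906 to 20.03 ± 10.9 CPM, 911-fold (595 to 1475), cytochrome c550 (MIT1002_3111) from 3866 to 7.62 CPM and the TonB receptor MIT1002_3124 from 6715 to 23.6 CPM. The histidine kinase MIT1002_3631 and the LuxR regulator MIT1002_3630 also fell, the latter to 1 count at 48 h (569-fold, 98.8 to 22791). Isocitrate lyase (MIT1002_2613) of the glyoxylate shunt stood at 3067 CPM at 2 h, 19706 at 6 h and 28.5 at 12 h, and malate synthase (MIT1002_2611) at 996, 4322 and 49.1. For the aldehyde dehydrogenase the 12 h libraries had a mean of 3963 and an SD of 5801 CPM. The acetate permease ActP (MIT1002_1652) went from 3799 CPM at 2 h to 279 at 4 h and 23865 at 12 h, and the pullulanase MIT1002_3288 from 388 at 2 h to 12621 ± 4854 at 12 h; these genes were chosen for their abundance or list after their values were seen.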

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

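The tests of read sharing between copies, of a difference present before addition, of Alteromonas reads on the rising genes, of fold changes after thinning, of a set difference between libraries, of the rate of Alteromonas counts per library, of the profile of each raised library by bootstrap, of growth in an axenic culture and of carry-over between libraries of 6 and 12 h were chosen only after the result was seen.

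Differences between the cultures departed from those before addition in 62, 63 and 69 genes at 12, 24 and 48 h by a test of the difference itself. The most coherent part was the fall of the high-light-inducible genes. A loss of short genes as a whole from the co-culture libraries would have lowered the other genes of at most 294 bases of coding length too. The lowest median of these 439 genes was 0.0178 at the 3 times. Short genes, 22.5% of the other genes with a length, made up 74.6%, 44.1% and 51.2% of those called lower at 12, 24 and 48 h. They also made up 1 of 3, 37 of 72 and 26 of 52 of those called higher. The 3 higher genes at 12 h are too few to weigh, and short genes called higher cannot exclude a loss of other short genes. A loss limited to some short genes is therefore not settled at any of the 3 times. If reads had moved between near-identical copies, the summed CPM would have been equal, but it was 64.4% of the axenic value or less. A difference already present before addition does not account for it either, since at least 11 members departed from that difference at each time. Unequal numbers of counts do not account for the calls, since at least 13 members were still called lower after thinning. Thinning leaves the share of each gene unchanged on average, so it cannot test a bias tied to the depth of a library. A set difference between libraries was not weighed for these genes. It cannot be told apart from a response, since no batch label exists. A response to the heterotroph remains as a hypothesis beside it, found and tested on the same data.

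The 42 genes higher at both 24 and 48 h form another pattern, of which 27 are hypothetical. Unequal depth as the source of these calls stays undecided. Of the 42 genes, 47.6% were still called higher at both times after thinning, short of the bound set beforehand for arguing against depth. The median standard error of a gene at 24 h went from 0.15 to 0.21 with fewer counts. Of the 41 genes tested after thinning all lay above 0 at both times. Their medians were 0.75 ± 0.08 at 24 h and 0.62 ± 0.06 at 48 h (standard error) against 0.71 and 0.77 before. These folds cannot decide, since thinning leaves the share of each gene unchanged on average. Alteromonas reads are at odds with the gap at 2 h (42 of 42 genes above 0 at a share of 2.54%, but 11 at 6 h at 10.7%), with the median of 0.0592 at 12 h, when the share was highest, and with 20 other, conserved genes listed beforehand as open to such reads (medians 0.01 at 24 h and 0.00 at 48 h, 0 called), yet they stay open for the 42 genes at 24 and 48 h, since the Alteromonas transcripts had changed by 24 h (Spearman correlation with 12 h 0.846) and the mean log2 CPM in co-culture went from 6.97 at 12 h to 7.64 at 24 h, against 6.97 and 6.70 in axenic culture. A set difference between libraries cannot be told apart from a response of these genes, since their medians were 0.47 and 0.46 at 2 and 4 h but -0.09 and 0.06 at 6 and 12 h, fold changes at 2 and 24 h correlated across genes (Spearman 0.49; genes are not independent replicates), and no batch label exists.

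Counts on Alteromonas genes were raised in 3 axenic libraries, above the 89 to 187 counts of the other 21 libraries that should hold none: 1219 counts at 6 h in replicate 3 (0.0530%, exact 95% interval 0.0501 to 0.0560%), 449 at 12 h in replicate 1 (0.0212%) and 1929 at 48 h in replicate 2 (0.0827%). Prochlorococcus reads on Alteromonas genes are argued against at 6 and 48 h, where the share lay above the highest of the 21 (0.0298%, interval 0.0247 to 0.0356%), but stay open at 12 h, which rests on that library alone (axenic, 2 h, replicate 2, the shallowest; without it the highest was 0.0118%, interval 0.0101 to 0.0136%); the share of counts in genes with counts before addition, at most 47.2%, was set aside as a test, since the co-cultures themselves had 44.9%. Carry-over from co-cultures of the same time is argued against at 6 and 12 h, where another time gave the higher correlation in 100% of 1000 bootstrap draws of genes (0.353 with the own time against 0.534, and 0.261 against 0.411). At 48 h it stays open, since the own time gave 0.575 against 0.557 with 24 h and was highest in 97.2% of draws, short of the bound set for a decision, while against single co-culture libraries the values were 0.574 and 0.567 and another time was highest in 10.1% of draws. Growth of Alteromonas in the 6 h culture is argued against only if that culture was sampled again. The highest share at 12 and 24 h was 0.0212%. That comparison stops at 24 h, and growth as the source of the 48 h counts (0.0827%) was not tested. Carry-over between libraries of 6 and 12 h may remain, given the 0.534 of the 6 h library with the 12 h co-cultures.

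Other groupings of the libraries were tried for every count. With 3 against 3 libraries only 10 groupings exist, too few for a share under 0.05. The real counts at 2, 4, 6, 12, 24 and 48 h were 1, 0, 5, 91, 215 and 181, and the highest of the other groupings 0, 0, 0, 1, 2 and 0; for the departures the real counts at 12, 24 and 48 h were 62, 63 and 69 and the highest other 0, with 0 in both at 2, 4 and 6 h. Before addition the real count was 0 and the highest other 153, which points to a structure of the samples, since replicate 1 of each set stood apart. For the axenic time course the real grouping called more genes than any other (586 against a highest of 362 in 100 groupings), a share under 0.05. The same held for Alteromonas (2526 against 636). The 362 and 636 genes are not counts from chance alone, since a random regrouping can keep some libraries of a time together. This test therefore cannot clear single genes among the calls of chance, nor give their rate of false calls.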

How the results depend on the processing

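The alternatives without 3 libraries that stood apart and without the 3 axenic libraries with raised Alteromonas counts were chosen only after the result was seen. Among named genes 69 results gave 1096 alternative values, of which 927 kept their direction and side of the threshold, 168 lost the threshold and 1 reversed, bioD at 24 h after thinning (0.0023, adjusted p = 0.998). With library totals only, 16 genes were called at 6 h, and the number of genes changed over time in axenic cultures was 1127. After thinning the counts were 0 at 2 h, 2 at 4 h, 60 at 12 h, 117 at 24 h, 41 and 42 for the departures at 24 and 48 h, 267 for the axenic time course and 1284 for Alteromonas. With only the 6 libraries of a time they were 2 at 2 h, 29 at 4 h, 25 at 6 h and 330 at 24 h, and with only 12 libraries the departures at 48 h numbered 45. Without the 3 libraries that stood apart they were 5 at 2 h, 18 at 6 h and, for departures, 1 at 2 h and 105 at 24 h; without the 3 axenic libraries with raised Alteromonas counts, 0 at 6 h and 307 in the axenic time course. The cause was not tested, apart from fewer counts after thinning and fewer libraries in smaller fits. Leaving out each replicate gave 0 to 0 genes before addition, 0 to 5 at 2 h, 0 to 1 at 4 h, 0 to 6 at 6 h, 75 to 90 at 12 h, 119 to 202 at 24 h and 108 to 198 at 48 h; departures ran from 0 to 0 at 2, 4 and 6 h, 47 to 60 at 12 h, 49 to 81 at 24 h and 46 to 89 at 48 h, the axenic time course from 268 to 327 and Alteromonas from 2181 to 2297. An estimated correlation ended 9 of 13 list calls by camera between the cultures (fry 7), 33 of 36 in the axenic time course and 8 of 24 for Alteromonas. Among the medians of all genes for co-culture against axenic culture at each time, the largest shift under another scaling was 0.059. The axenic time course and Alteromonas were not part of that comparison.

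The replicate number was also tried as a block. Whether the numbers pair the samples is not settled. At no time were the correlations of same-numbered libraries all above 0.1, and at no time did every library correlate best with its own number. The correlations were 0.58, -0.16 and 0.44 before addition and 0.33, -0.05 and 0.20 at 48 h, but -0.12, -0.23 and 0.004 at 6 h. With the replicate block 14 genes were called at 6 h, and 0, 1, 0, 89, 216 and 198 at the other times; the departures were 0, 0, 0, 62, 73 and 73, the axenic time course gave 590 and Alteromonas 2499. DESeq2 tested the time courses by a likelihood ratio test.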

Other observations

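The test of neighbouring genes and the comparison of each co-culture time with the time before addition were chosen only after the result was seen.

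Genes lower at 12, 24 and 48 h lay near high-light-inducible genes. Of 37 other lower genes with a place in the RefSeq order, 16 (43.2%) lay within 3 genes of 1 of the 17 placed high-light-inducible genes, against 55 of 1906 remaining genes (2.89%). Fisher's exact test gave a two-sided p of 1.25e-14, in which neighbouring genes are not independent replicates. Of 6 tested members of the hypothetical family FIG00940767, 4 were lower at all 3 times.

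The co-cultures changed over time as well. Against 12 h before addition 66, 114, 247, 165, 322 and 344 genes were called in co-culture at 2, 4, 6, 12, 24 and 48 h. In Alteromonas the sucrose-specific TonB receptor MIT1002_1864 went from 10235 ± 807 CPM at 2 h to 52.6 ± 8.12 at 48 h, 193-fold lower, and catalase (MIT1002_1576) from 2 counts to 909, a ratio of 55.1 (95% interval 15.2 to 456). The nitrogen regulator P-II (MIT1002_3192) had 10 counts at 2 h and 0 at 48 h, a fall with an exact 95% lower limit of 18.5-fold.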
